A study of Oryza sativa Japonica Group with 24 samples.

How the data were processed

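The data are read counts per annotated feature from polyadenylated RNA of rice roots in 24 libraries, 3 biological replicates in each of 8 groups. Per the labels, 6 roots were pooled for each library and a directional library kit was used. The deposited table holds counts, whole numbers that sum to a different total in each library. Its features are 2079 gene symbols, 35751 locus identifiers and 54162 non-coding identifiers. The aligner, the counter, the genome build, the annotation release and the strand setting are not given in the sources used here; the labels name DESeq2 without a version. Each column was matched to its sample by the description above it, and groups were taken from the labels. A treatment field of the inoculated samples reads BH72, BH73 and BH74 over replicates 1 to 3; all were taken as BH72, the strain named in their titles. The libraries held 12.9 to 20.4 megareads. Between replicates of a group the chi-square per gene was 4.61 to 49.3 over 24 pairs of libraries, where counting error by itself gives about 1. Reads copied by amplification are not independent molecules, so any statement about depth covers counting error only. Ribosomal RNA took up to 0.420% and non-coding features up to 1.41% of the reads.

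Counts were tested in R 4.3.3 with edgeR 4.0.16 by its quasi-likelihood F test, with robust estimates of the spread, trimmed-mean (TMM) scaling (factors 0.948 to 1.04) and the default filter on low counts (minimum count 10, minimum total 15). All 24 libraries were fitted together with 1 mean per group. The comparisons were inoculated against non-inoculated roots in each of 4 settings, the difference of that effect between media and between the 3 days, 400 against 20 mg of malic acid per litre without bacteria, and day 7 against day 1 without bacteria. Features with a Benjamini-Hochberg adjusted p under 0.05 are called. CPM is counts per megaread after this scaling. No test of 3 against 3 by permutation can reach 0.05 here, since 10 splits allow no share under 0.1, so p-values rest on the edgeR and limma models. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

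Gene lists were tested with camera (limma 3.58.1) with its preset correlation of 0.01, beside camera with an estimated correlation and fry, and adjusted over all lists with at least 5 tested members within a comparison. The lists planned by locus identifier and by product name could not be used, since the reference does not pair the locus identifiers of the table with names. They were rewritten with the symbols of the table after its identifiers had been read but before any comparison was computed. This gave 49 lists, 46 of them with enough tested members. For lists, the count of called members is given over all features and adjusted over the list alone.

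Genes named in the text follow a fixed rule. For an inoculation comparison it takes the 10 risen and 6 fallen genes with the largest log2 change among called genes with a symbol, a mean of at least 1 log2 CPM and no overlap between the 3 and 3 libraries (10% of genes by chance). For the other comparisons it takes 5 and 5, and for the test between days the 8 with the smallest p. It adds up to 3 called members of each list with the smallest p, or the most abundant member of a described list without any. Features without a symbol were passed over by the rule: 1 risen and 1 fallen at day 1, 29 and 15 in boosted medium, 7 and 15 for malic acid, 222 and 8 for age, 40 and 42 in the 6-library fit of day 3 and 72 and 65 in the blocked fit of day 1. Of the genes this rule gives, the text prints those of the groups it describes, and 1 of them is not reported here.

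Comparisons, tests, the filter, the main alternatives, the idea behind each list and the rule for named genes were set before the data were examined. Alternatives tried were DESeq2 1.42.0 as the test or for scaling, no filter, a filter of at least 1 CPM in at least 6 libraries, no robust spread, the replicate number as a block, the compared groups alone, and each library left out in turn. Chosen after the data were seen were limma-voom with sample quality weights, a block nested in day and medium, the compared groups with a block, the 18 libraries of the standard medium, both boosted replicate 2 or both day 1 replicate 1 libraries left out, and for age the omission of features without a read at day 1 and day 3 in place of day 1.

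Whether replicate numbers pair the libraries was checked by correlating, across genes, the deviation of an inoculated library from its group mean with that of each control; genes are not independent replicates. The correlation with the control of the same number was 0.745, 0.547 and 0.559 at day 1 and 0.285, 0.135 and 0.108 at day 7. Each was above that with the other numbers and above a minimum of 0.1, so these days were taken as paired, though weakly at day 7. At day 3 it was 0.0361, 0.103 and 0.0297, also above that with the other numbers but mostly under 0.1. In boosted medium it was -0.357, -0.379 and -0.330. The block at day 7 in the 6 libraries gave 0 calls (edgeR; 1950 at an unadjusted p under 0.05). The method was tested on simulated data with 200 changed genes. With the spread of each group kept, the 24-library fit recovered 65.7% of 2-fold changes at day 1 with 55 false calls, 62.7% at day 3 with 0 false calls and 59.7% in boosted medium with 64 false calls, and the 6-library fit of day 3 recovered 83.6% with 24 false calls. The simulated libraries were drawn independently of each other, without pairs, and no blocked fit was run on them. How many false calls the blocked fit of day 1 gives is therefore not known. A simulated list of 20 genes raised 1.5-fold was called (limma, adjusted p = 3.1e-26) and 0 of 46 others were. For this list the spread was the same in all groups and genes were drawn independently of each other. It therefore cannot show how often the list test with its preset correlation errs when genes are correlated.

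Marker lists for green tissue, dividing cells and seed were run with the rest. The seed list had 6 tested members and passed in no comparison; its adjusted p was 0.586, 0.811, 0.573 and 0.746 for days 1, 3, 7 and boosted medium, 0.886 for malic acid, 0.953 for the difference between media and 0.870 for age. Lists of root hair, endodermis and organelle genes had no or too few members with a symbol. Bacterial reads, plant growth and colonization were not analysed here, and the sequence reads were not used here.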

Results

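Polyadenylated RNA of rice roots (Oryza sativa ssp. japonica, cultivar Nipponbare) was sequenced in 24 libraries, each made from 6 pooled roots. The roots had been grown in hydroponic culture with or without Azoarcus olearius BH72, a nitrogen-fixing bacterium that lives inside grass roots without causing disease. They were harvested 1, 3 or 7 days after the bacteria were added to medium with 20 mg of malic acid per litre, or after 3 days in medium with 400 mg per litre, which the labels call boosted colonization. Malic acid is a carbon source for the bacterium. Each of these 4 settings had 3 inoculated and 3 non-inoculated libraries, so the 24 libraries form 8 groups of 3 biological replicates, from seedlings 6, 8 or 12 days old at days 1, 3 and 7.

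The libraries held 12.9 to 20.4 megareads (M) of counted reads, with a median of 17.3 M. Group means (SD, n = 3 each) were 13.8 ± 1.30 M for inoculated and 14.1 ± 0.623 M for non-inoculated roots at day 1. At day 3 they were 18.6 ± 0.963 and 17.1 ± 2.36 M, in the boosted setting 17.4 ± 2.96 and 19.2 ± 0.968 M, and at day 7 17.6 ± 2.71 and 16.7 ± 1.99 M. The 10 most abundant features took 2.32% to 5.06% of a library. Of 91992 listed features 37334 had a read in some library, and 24848 were abundant enough to be tested, 1760 of them listed under a gene symbol. Expression is given in counts per megaread (CPM), as mean ± SD over 3 libraries.

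The day 1 libraries differed from the others in which features had any read. None (0) of the 2957 non-coding features with a read at days 3 and 7 had a read at day 1. In all, 316 features had no read in the 6 day 1 libraries and at least 1 CPM in each of the 18 later ones. They comprised 268 unnamed loci, 43 non-coding features and the symbols ADK-B_1, D14L_2, ITPK5, PAC1A_1 and PAC1A_2, and held 0.804% to 1.78% of the reads of the later libraries. On the 1000 most variable features the first principal component held 80.3% of the variance and parted day 1 from the later days, but 457 of these features had no read at day 1. Without such features it held 58.9%, still parted day 1 from the rest, and the second component (19.3%) parted day 7 from day 3. Inoculated and non-inoculated libraries of the same day lay together on both components.

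**Figure D1:**
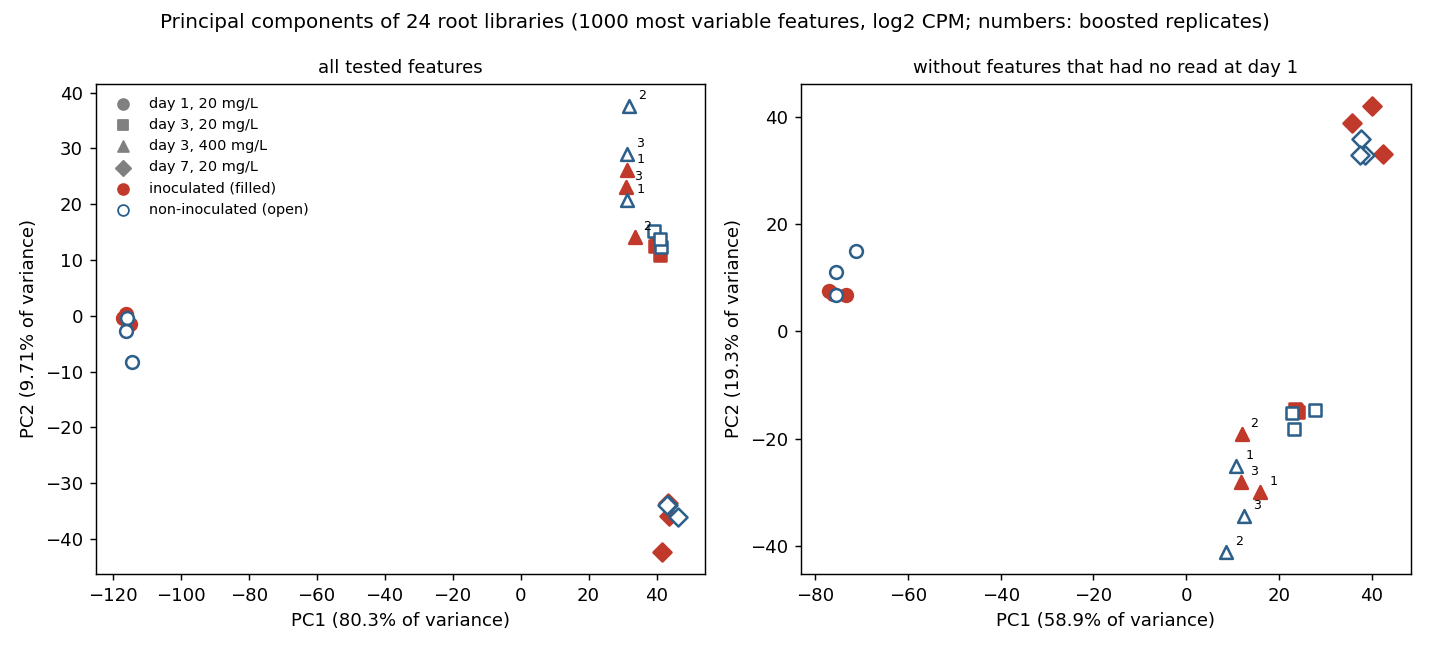
Principal components of log2 CPM in the 24 libraries, each point 1 library, shaped by day and medium and filled red if inoculated, with boosted replicates numbered, with all tested features on the left and without those that had no read at day 1 on the right; axes give each component's share of the variance. Libraries group by day and medium, and the first component falls from 80.3% to 58.9% of the variance without those features.

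The first question was what the root changes within 1 day of meeting the bacterium. OPR4, of the 12-oxophytodienoate reductase family, whose best known members act in jasmonate synthesis, fell from 56.2 ± 14.4 to 20.2 ± 4.42 CPM. Of 17 glutathione transferases and glutaredoxins, enzymes of detoxification and redox balance, 14 were lower, and the list passed its test (adjusted p = 4.84e-07, and adjusted p = 0.0242 with an estimated correlation). When in the 6 day 1 libraries alone each inoculated one was set against the control of the same replicate number, the glutathione transferase GSTU1 fell, and the glutamine synthetase GLN1-2 and the ammonium transporters AMT1-1 and AMT1-2 rose. In the fit of all 24 libraries 5 of 24848 features passed (edgeR), 1 higher and 4 lower. In simulated data with the spread of each group kept, this fit gave 55 false calls at day 1. OPR4 fell by 1.48 on the log2 scale (SE 0.19, edgeR adjusted p = 0.00606). Among the unnamed loci, chosen after their values were seen, OS05G0114400 rose by 1.79 (edgeR adjusted p = 0.014) and OS05G0215300 fell by 1.65 (edgeR adjusted p = 0.0282).

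At day 1, 6 of the 46 lists of genes fixed beforehand passed the list test, although no member of these lists passed by itself in the fit of 24 libraries. Without inoculated replicate 1, and likewise without non-inoculated replicate 3, 2 lists passed. Both replicate 1 libraries stood apart from their groups. The chi-square per gene was 32.0 and 32.1 for the inoculated one against 7.32 between the other two, and 28.7 and 32.2 for the non-inoculated one against 9.36. The non-inoculated one also held 31.1 CPM of the Rubisco gene RBCS, against 0 and 0.0745 in the other two controls, and 21.8 CPM of RBCS-A, against 0.622 and 1.79. The glutathione transferases and glutaredoxins had a median log2 change of -0.19 and a mean of -0.43, with 0 higher and 2 lower when adjusted over the list alone, and were the sole list of the 6 to keep the call with an estimated correlation. Of 12 ascorbate peroxidases, catalases and superoxide dismutases 11 were lower (median -0.10, adjusted p = 0.00739, adjusted p = 0.264 with an estimated correlation). Of 32 expansins, which loosen cell walls, 26 were higher (median 0.24, adjusted p = 0.0014, adjusted p = 0.823 with an estimated correlation). Of 40 genes of DNA replication and mitosis 32 were higher (median 0.14, adjusted p = 1.09e-05, adjusted p = 0.823 with an estimated correlation). Of 22 Aux/IAA genes, repressors of auxin responses, 18 were higher (median 0.11, adjusted p = 0.0102), and of 29 ribosomal protein genes 27 (median 0.10, adjusted p = 0.0204), with adjusted p = 0.823 and adjusted p = 0.89 with an estimated correlation. Adjusted over the list alone, 0 members of these last 5 lists passed.

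Replicate numbers pair the day 1 libraries (correlations of 0.745, 0.547 and 0.559 across genes), and a fit of these 6 libraries with the replicate number as a block, chosen after the data were seen, called 670 of 21074 features, 202 higher and 468 lower, 84 of them with a symbol. With all 24 libraries the replicate number as a block gave 8 calls, and a block nested in day and medium 6. GSTU1, a glutathione transferase, fell from 211 ± 19.8 to 73.6 ± 12.2 CPM (log2 -1.54, SE 0.0905, edgeR adjusted p = 3.18e-05). GSTZ5 fell from 206 ± 75.6 to 85.7 ± 15.5 CPM (log2 -1.23, edgeR adjusted p = 0.0068), and GSTF2 fell by 0.49 on the log2 scale (edgeR adjusted p = 0.00731). In all, 4 of 15 tested genes of that list fell, 7 when adjusted over the list alone. The ascorbate peroxidase APX2 fell by 0.38 and the superoxide dismutase SODCP by 0.31 on the log2 scale. Of 14 nitrogen uptake and assimilation genes 3 rose and 1 fell: AMT1-1 reached 147 ± 42.1 against 96.5 ± 21.9 CPM (log2 0.58, edgeR adjusted p = 0.00152), AMT1-2 rose by 0.90 and GLN1-2 by 1.02 on the log2 scale. NAC71, a NAC family transcription factor, rose from 76.4 ± 7.19 to 129 ± 12.1 CPM (log2 0.74, edgeR adjusted p = 0.00028). LPR5, of the multicopper oxidase family tied to phosphate sensing in roots, rose from 7.11 ± 1.85 to 22.8 ± 2.48 CPM (log2 1.68, edgeR adjusted p = 5.51e-05), and PDC1, a pyruvate decarboxylase, from 0.496 ± 0.268 to 4.99 ± 3.13 CPM.

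The same blocked comparison moved single members of other groups. The laccases LAC19 and LAC10, enzymes of lignin polymerisation, fell by 1.85 and 0.81 on the log2 scale while LAC8 rose from 2.67 ± 2.26 to 7.46 ± 6.90 CPM. The beta-glucosidase BGLU22 fell by 1.21, the potassium transporter HAK16 by 0.86, the aquaporin PIP1-3 by 0.49, the sugar exporter SWEET14 by 0.56 and the dehydration-responsive LEA3 by 0.99. The replication helicase subunit MCM5 rose by 0.34 (3 of 39 genes of DNA replication rose, 9 when adjusted over the list alone) and IAA31 and IAA12 by 0.36 and 0.41 (2 of 21 Aux/IAA genes). Without the block the same 6 libraries gave 0 calls in edgeR, with 811 features at an unadjusted p under 0.05, so the 670 calls rest on the pairing together with leaving out the other 18 libraries. The blocked fit was not run on the simulated data, so its false calls are not known. With 24 libraries DESeq2 called 71 and limma-voom with quality weights 27 features, and OPR4 lost its call without inoculated replicate 2 (edgeR adjusted p = 0.148) and without non-inoculated replicate 2 (edgeR adjusted p = 0.0514). Leaving out either of these replicate 2 libraries left 0 calls, so the unnamed loci lost theirs too.

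**Figure D2:**
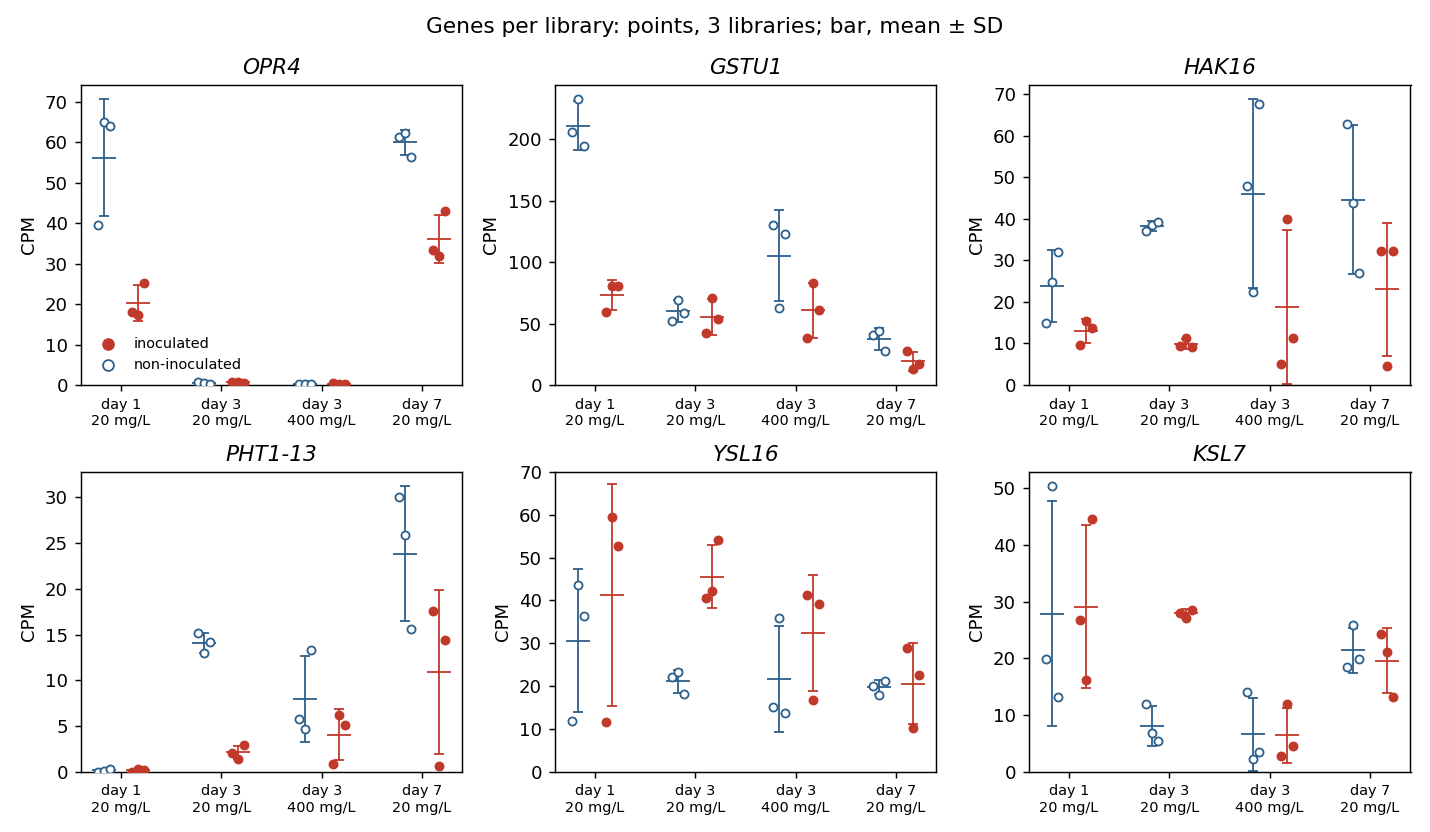
CPM of OPR4, GSTU1, HAK16, PHT1-13, YSL16 and KSL7 in each library (points) with the group mean and SD (n = 3), inoculated beside non-inoculated for each day and medium. OPR4 stayed under 1 CPM in all 12 day 3 libraries, and HAK16 at day 3 lay at 9.97 ± 1.19 CPM with and 38.3 ± 1.14 CPM without bacteria.

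The second question was the state of the root 3 days after inoculation. In the 6 day 3 libraries by themselves, 3 of 7 genes of diterpenoid phytoalexin synthesis and the metal transporters YSL16 and ZIP1 rose with bacteria, while 2 of 13 genes of phosphate transport and 2 of 21 potassium transporters fell. KSL7 and KSL4, diterpene cyclases of the phytoalexin pathways, reached 28.0 ± 0.729 against 8.10 ± 3.48 CPM and 3.52 ± 1.37 against 0.762 ± 0.312 CPM. The potassium transporter HAK16 fell from 38.3 ± 1.14 to 9.97 ± 1.19 CPM and the phosphate transporter PHT1-13 from 14.1 ± 1.06 to 2.13 ± 0.734 CPM. These are calls of the fit of the 6 libraries compared. In the fit of all 24 libraries 0 of 24848 features passed at day 3 (edgeR), with 899 at an unadjusted p under 0.05, while DESeq2 called 8 and limma-voom with quality weights 100.

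The 6-library fit called 156 of 23343 features at day 3, 54 higher and 102 lower, 20 with a symbol. Of 7 tested diterpenoid phytoalexin genes 3 rose: KSL7 (log2 1.78, SE 0.25, edgeR adjusted p = 0.044), KSL4 (log2 2.21, edgeR adjusted p = 0.0378) and the cytochrome P450 CYP701A8 (log2 0.64, edgeR adjusted p = 0.033). CYP701A7, a cytochrome P450 of the same subfamily, fell from 6.57 ± 0.989 to 0.777 ± 0.484 CPM. YSL16, a carrier of metal chelates, rose from 21.1 ± 2.68 to 45.6 ± 7.40 CPM (edgeR adjusted p = 0.0119). The metal transporter ZIP1 rose from 13.5 ± 2.74 to 24.2 ± 2.1 CPM (log2 0.84, edgeR adjusted p = 0.0296) and the metallothionein MT1B by 0.63 on the log2 scale. ISPG, an enzyme of the plastid isoprenoid pathway, rose from 230 ± 18.7 to 348 ± 36.3 CPM. Of 21 HAK and HKT potassium transporters 2 fell, HAK16 (log2 -1.94, SE 0.0889, edgeR adjusted p = 1.73e-05) and HKT1 (log2 -0.64, edgeR adjusted p = 0.00629). Of 13 phosphate transport and signalling genes 2 fell, PHT1-13 (log2 -2.71, SE 0.194, edgeR adjusted p = 0.000317) and PHT1-4 (log2 -1.33, edgeR adjusted p = 0.00485). The alternative oxidase AOX1B fell by 1.99, the calmodulin-like CML21 by 1.81, FLOT1 by 0.94, the trehalose-6-phosphate phosphatase TPP2_2 by 0.67, BGLU30 by 0.54 and GSTZ5 by 0.38 on the log2 scale.

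In the list test on 24 libraries 5 of 46 lists passed at day 3, with 0 members called in any of them over all genes or adjusted over the list alone, and each lost its call with an estimated correlation (adjusted p = 0.667). The count of lists was 2 with no filter, 3 to 6 with 1 library left out and 9 in the 6 libraries by themselves. Of 10 diterpenoid phytoalexin genes 7 were higher (median log2 0.39, adjusted p = 0.0376). All 6 type-A response regulators, early genes of the cytokinin response, were higher (median 0.21, adjusted p = 0.0102). All 9 cellulose synthases were lower (median -0.24, adjusted p = 0.0102), as were 16 of 19 calmodulin-like proteins (median -0.18, adjusted p = 0.0102), and the 12 laccases had a median of -0.34 (adjusted p = 0.0499). The spread between day 3 replicates was small, with biological coefficients of variation of 8.14% and 8.60%, against up to 26.1% in other groups. With the 3 inoculated day 7 libraries added to the 6 of day 3, the 156 calls became 0.

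The third question was the response at day 7. No feature passed at day 7 (0 of 24848, edgeR; 2406 at an unadjusted p under 0.05, 101 by DESeq2 and 7 by limma-voom with quality weights). Several lists of the cell wall and of jasmonate, and the nitrogen list, lay lower in inoculated roots with a preset correlation, but 0 lists passed with an estimated correlation or by fry. In some measures of make-up the libraries also did not overlap (10% by chance for each measure). Total reads, the share of reads on symbols and the number of features with a read did overlap. Ribosomal RNA is counted among the non-coding features, so their shares are not independent of each other. Ribosomal RNA took 0.143%, 0.159% and 0.137% of the inoculated and 0.199%, 0.350% and 0.208% of the non-inoculated libraries. Non-coding features took 0.478%, 0.535% and 0.464% against 0.683%, 1.19% and 0.712%, and the 10 most abundant features 4.66%, 4.72% and 5.06% against 4.04%, 3.81% and 4.06%. Of 46 lists 13 passed as lower and 1 as higher, none of them with an estimated correlation (adjusted p = 0.253 for 9 of the lower lists), with 0 members called over all genes. Adjusted over the list alone, 5 nitrogen genes and 1 gene each of the jasmonate, TIFY and abscisic acid lists were lower and no others passed. The 29 phenylpropanoid, lignin and flavonoid genes had a median log2 change of -0.25 (adjusted p = 0.000356), the 12 laccases -0.45 (adjusted p = 0.00148), the 32 expansins -0.34 (adjusted p = 0.000172) and the 9 cellulose synthases -0.32 (adjusted p = 5.51e-05). The 19 nitrogen uptake and assimilation genes had a median of -0.24 and a mean of -0.81 (adjusted p = 0.000172), and the 16 aquaporins a median of -0.29 (adjusted p = 0.00155). The 9 TIFY proteins, repressors of jasmonate responses, had a median of -0.50 (adjusted p = 0.000917) and 6 jasmonate biosynthesis genes -0.32 (adjusted p = 0.0447). None of these calls held with an estimated correlation (adjusted p = 0.253 for most, adjusted p = 0.26 for cellulose synthases and adjusted p = 0.306 for jasmonate biosynthesis).

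The other lower lists at day 7 were germin-like proteins (6 genes, median -0.52, adjusted p = 0.0279), beta-glucosidases (16, -0.24, adjusted p = 0.00816), abscisic acid and dehydration genes (9, median -0.28, mean -0.69, adjusted p = 0.0264), calmodulin-like proteins (19, -0.12, adjusted p = 0.0165) and calcium-dependent protein kinases (23, -0.11, adjusted p = 0.0404), with adjusted p = 0.253 for the first 3 and adjusted p = 0.306 for the last pair with an estimated correlation. The 18 genes of photosynthesis and chlorophyll synthesis, a marker of green tissue, were higher (median 0.46, adjusted p = 0.0447, adjusted p = 0.633 with an estimated correlation). Of the most abundant members, glutamine synthetase GLN1-1 lay at 509 ± 95.5 against 678 ± 27.1 CPM (log2 -0.41, edgeR adjusted p = 0.302), CESA3 at 546 ± 149 against 665 ± 59.8 CPM (edgeR adjusted p = 0.532), and LAC3 had a log2 change of -0.70 (edgeR adjusted p = 0.494). SALT, a dehydration-responsive gene, lay at 57.2 ± 43.4 against 691 ± 776 CPM (edgeR adjusted p = 0.296), and RBCS-A, the small subunit of Rubisco, at 205 ± 87.3 against 137 ± 29.0 CPM (edgeR adjusted p = 0.799). Inoculated replicate 2 stood apart from its group, with a chi-square per gene of 48.3 and 49.3 against 16.2 between the other two and the lowest quality weight of all libraries (0.232). It held 1.20 CPM of the ammonium transporter AMT1-3, for example, against 42.7 and 27.03. Single libraries decided part of this: of the 13 lower lists 9 passed without inoculated replicate 2 and 7 without inoculated replicate 3. The green list had adjusted p = 0.389 without inoculated replicate 1, 0.398 without inoculated replicate 2 and 0.0919 without non-inoculated replicate 3. Without inoculated replicate 1, 236 features passed, 103 of them lower. The 6 day 7 libraries with the replicate number as a block gave 0 calls (edgeR; 1950 at an unadjusted p under 0.05).

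**Figure D3:**
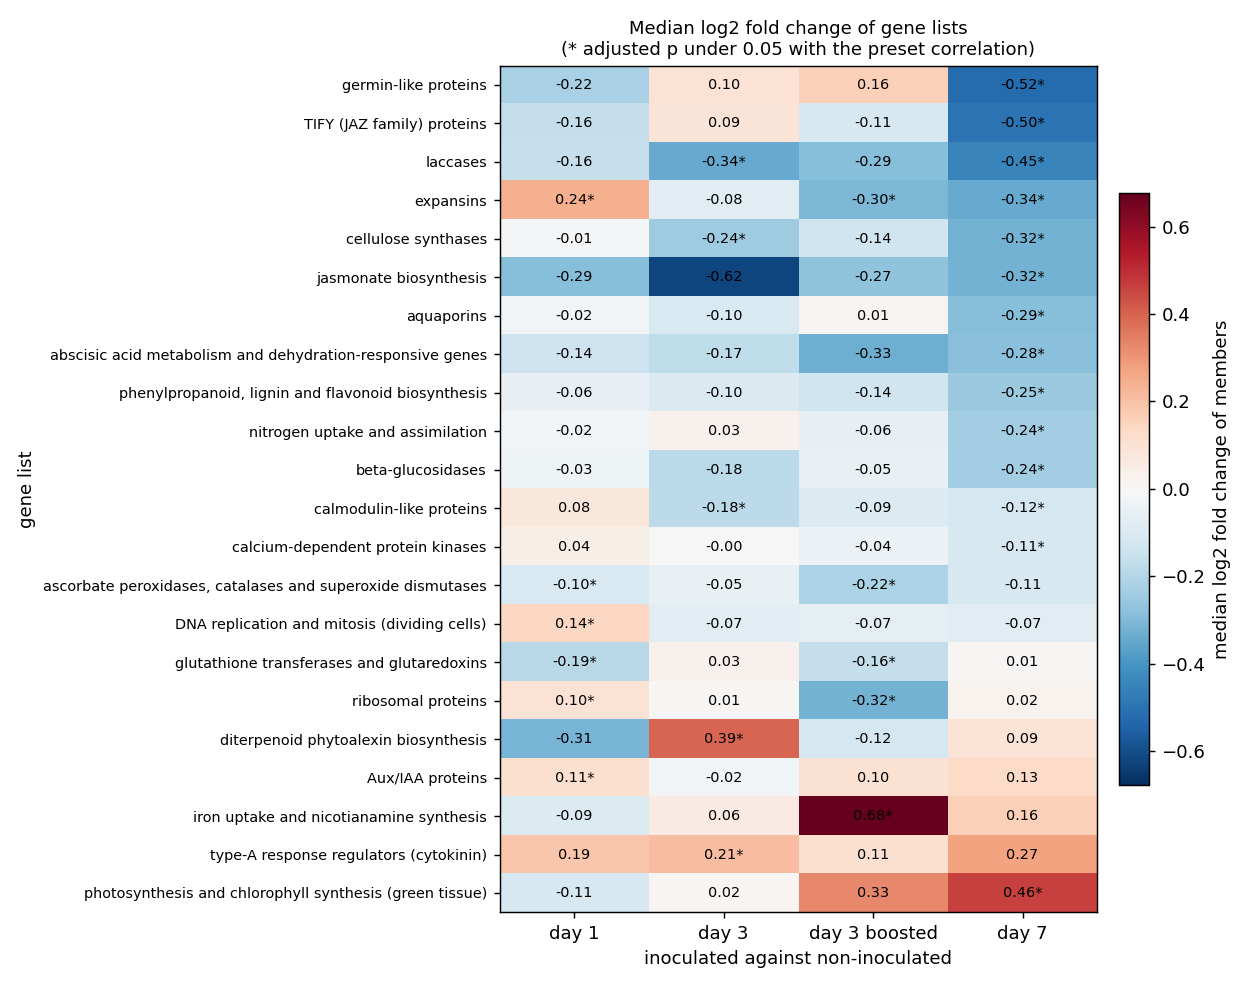
Median log2 change, inoculated against non-inoculated, of 22 gene lists (vertical axis) in the 4 inoculation comparisons; an asterisk marks an adjusted p under 0.05 in the list test with a preset correlation. At day 7, 13 of the 14 marked lists lie below 0, and of all marked lists the glutathione transferases at day 1 alone keep the call with an estimated correlation.

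The fourth question was what 400 mg of malic acid per litre, meant to raise bacterial growth, does to the response at day 3. With it, 62 of 24848 features passed (edgeR), 41 higher and 21 lower, 4 with a symbol. With DESeq2 size factors 72 were higher and 20 lower, with the stricter filter 70 and 21, and with no filter 31 and 11. In simulated data with the spread of each group kept, this fit gave 64 false calls in boosted medium, and another split of the same 6 libraries gave 739 calls. The replicate 2 libraries lay across the groups: the haemoglobin HB2 had 53.4, 0.148 and 72.7 CPM in the libraries labelled inoculated and 0.0564, 48.6 and 0.815 in the others. Both replicate 2 libraries also differed in make-up, with 0.297% and 0.420% ribosomal RNA against 0.133% to 0.177% in the other boosted libraries. The standard day 3 libraries held 0.287% to 0.412%. GATA19, a GATA family transcription factor, rose from 9.66 ± 1.38 to 15.6 ± 2.09 CPM (log2 0.69, SE 0.114, edgeR adjusted p = 0.021). The auxin response factor ARF6 rose from 67.1 ± 1.92 to 93.5 ± 7.64 CPM (log2 0.48, edgeR adjusted p = 0.021), and the calcium-dependent protein kinase CPK17 from 37.1 ± 1.97 to 49.9 ± 3.20 CPM (log2 0.43, edgeR adjusted p = 0.0199). SPDSYN1, a spermidine synthase, fell from 138 ± 5.62 to 98.7 ± 4.18 CPM (log2 -0.49, edgeR adjusted p = 0.021). Among unnamed loci, chosen after their values were seen, OS07G0430501 rose by 3.61 and OS07G0180300 by 1.37 on the log2 scale, and OS07G0419200 fell by 0.81.

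With boosted colonization 5 of 46 lists passed, and 2 to 11 with 1 library left out. Of 29 ribosomal protein genes 28 were lower (median log2 -0.32, adjusted p = 1.59e-09, adjusted p = 0.819 with an estimated correlation; 14 lower when adjusted over the list alone). The 32 expansins were lower (median -0.30, adjusted p = 0.00561, adjusted p = 0.819 with an estimated correlation; 1 lower when adjusted over the list alone), as were 12 ascorbate peroxidases, catalases and superoxide dismutases (median -0.22, adjusted p = 0.00561, adjusted p = 0.399 with an estimated correlation) and 17 glutathione transferases and glutaredoxins (median -0.16, adjusted p = 0.0282). Of 10 genes of iron uptake and nicotianamine synthesis 9 were higher (median 0.68, adjusted p = 0.00611); both of these last lists had adjusted p = 0.733 with an estimated correlation. No member of these 5 lists passed over all genes, nor of the other three when adjusted over the list alone. The most abundant iron uptake gene, the iron chelate carrier YSL15, lay at 110 ± 71.2 against 26.9 ± 18.1 CPM (edgeR adjusted p = 0.251). Without non-inoculated replicate 3 the 62 calls became 0, without inoculated replicate 3 they became 1281 and without both replicate 2 libraries 550. The fit of the 6 boosted libraries alone called 0 in edgeR (2163 at an unadjusted p under 0.05), GATA19, ARF6, CPK17 and SPDSYN1 included.

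Whether the response at day 3 differed between the media was tested directly. The difference of the inoculation effects, boosted minus standard, was past the threshold for 0 of 24848 features (edgeR; 1467 at an unadjusted p under 0.05, 2 by DESeq2, 1 by limma-voom with quality weights). Among lists 6 of 46 passed, with 0 members called over all genes or adjusted over the list alone. Without inoculated boosted replicate 3, 80 features passed, and without both boosted replicate 2 libraries, which lay across their groups, 49. The 6 lists became 1 without non-inoculated day 3 replicate 2, and likewise without non-inoculated boosted replicate 1. The response was lower in boosted roots for 29 ribosomal protein genes (median difference -0.31 on the log2 scale, adjusted p = 4.6e-09), diterpenoid phytoalexin synthesis (-0.69), chitinases (-0.72), expansins (-0.23) and glutathione transferases (-0.20), and higher for HAK and HKT potassium transporters (0.20), with adjusted p = 0.0351 for these except 0.0428 for chitinases. With an estimated correlation none passed, with adjusted p = 0.741 for the ribosomal, diterpenoid and chitinase lists, adjusted p = 0.804 for expansins and adjusted p = 0.684 for the other two. KSL7, for example, lay at 6.41 ± 4.86 CPM with and 6.62 ± 6.45 CPM without bacteria in boosted medium. Each of these means includes a replicate 2 library that lay across its group, so their likeness does not show a lost response.

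Whether the response differed between days 1, 3 and 7 was tested with 2 degrees of freedom. No feature passed (0 of 24848, edgeR; 980 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom with quality weights). BURP7 and OPR4 had the smallest unadjusted p of the genes with a symbol, each with an edgeR adjusted p of 1. OPR4 lay at 36.1 ± 5.98 against 60.0 ± 3.15 CPM at day 7 (log2 -0.73, edgeR adjusted p = 0.268) and at 0.671 ± 0.103 against 0.438 ± 0.189 CPM at day 3. It was all but absent from every day 3 library, with and without bacteria (0.138 to 0.781 CPM). Its day 3 values, which the test between days includes, are therefore too low to read a response from. HAK16 was called at day 3 in the 6-library fit, and at day 1 in the blocked 6-library fit alone, which was chosen after the data were seen. It had log2 changes of -0.94 at day 7 (edgeR adjusted p = 0.64) and -1.28 in boosted medium (edgeR adjusted p = 0.351).

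Genes shared between the comparisons were counted next. In the 24-library fit 0 features were called in the same direction in any pair of the 4 inoculation comparisons. Days 3 and 7 had 0 calls in that fit, so only day 1 and boosted medium could share any. For them independent lists give 0.00165 higher and 0.00338 lower features, so this count says little about a shared response. In the 6-library fits, with the block at day 1 and among the 20571 features tested in all 4, the day 1 and day 3 calls shared 15 higher features (0.480 for independent lists, Fisher's exact test, one-sided p = 5.77e-19) and 15 lower ones (1.92 for independent lists, one-sided exact p = 7.1e-10). HAK16 and GSTZ5 were lower and ZIP1 was higher in both. Genes are not independent of each other, which this test takes them to be. Of the 156 features called at day 3, 110 of 143 tested had the same sign at day 1, 117 of 152 at day 7 and 118 of 154 in boosted medium. Tested as a set in those libraries they did not pass (fry in limma, adjusted p = 0.138, adjusted p = 0.177 and adjusted p = 0.214).

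The effect of malic acid by itself was read from the non-inoculated day 3 roots, and it passed the test in more features than any of the 4 inoculation comparisons. In 400 against 20 mg per litre 23 of 29 ribosomal protein genes, 11 of 32 expansins, 4 of 8 chitinases and 4 of 9 TIFY genes rose, and 13 of 18 photosynthesis genes fell. EXPA2, an expansin, rose from 15.5 ± 0.538 to 34.5 ± 3.92 CPM. RBCS-A fell from 45.9 ± 11.4 to 4.27 ± 2.75 CPM, and RBCS, a further Rubisco subunit gene, lay at 0.0175 against 10.4 ± 2.06 CPM. Of 24848 features 5892 passed (edgeR), 2894 higher and 2998 lower, 479 with a symbol.

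Of 46 lists 8 passed under malic acid, 7 higher and 1 lower, and each lost its call with an estimated correlation (adjusted p = 0.774 for DNA replication and adjusted p = 0.585 for the other lists). Of 29 ribosomal protein genes 23 rose (24 adjusted over the list alone; median log2 0.68, adjusted p = 1.21e-13), among them RPS4 (log2 0.78, SE 0.11, edgeR adjusted p = 0.000142) and RPS7 (0.58). Of 32 expansins 11 rose and 1 fell (median 0.62, adjusted p = 0.000372), among them EXPA2 (log2 1.15, edgeR adjusted p = 0.000106), EXPB3 (1.00) and EXPB6 (0.90). Of 9 TIFY proteins 4 rose (median 0.83, adjusted p = 0.00136), TIFY10C from 2.99 ± 0.418 to 11.2 ± 3.40 CPM (edgeR adjusted p = 0.000147). Of 8 chitinases 4 rose (median 1.34, adjusted p = 0.0103), among them CHT6 (log2 2.55), CHT8 (2.11) and CHT10 (1.21). Of 40 genes of DNA replication 12 rose and 2 fell (16 and 2 adjusted over the list alone; median 0.29, adjusted p = 0.00204): H2B.11 rose by 0.60, while MCM9 and RFC1 fell by 0.69 and 0.50. Of 17 glutathione transferases and glutaredoxins 4 rose (6 adjusted over the list alone; median 0.26, adjusted p = 0.0263), GSTU6 from 11.8 ± 3.55 to 49.8 ± 29.7 CPM. Of 21 genes of endoplasmic reticulum folding 6 rose (median 0.16, adjusted p = 0.0376), PDIL1-1 by 0.51. Of 18 photosynthesis genes 13 fell (14 adjusted over the list alone; median -1.61, adjusted p = 1.73e-06), among them CAO, which makes chlorophyll b (log2 -1.62, edgeR adjusted p = 0.000297), the regulator GLK1 (-1.76) and PETC (-1.60).

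Among the largest single changes under malic acid, CHS2, a chalcone synthase, rose from 1.23 ± 0.202 to 17.9 ± 9.15 CPM (log2 3.86, edgeR adjusted p = 0.00028), ADC2, an arginine decarboxylase, by 3.16 and the sugar exporter SWEET12 by 4.82 on the log2 scale. GLO1 fell by 2.98 and ADI1 by 2.87, and the clock gene PRR37 by 1.06. CPK17, which rose with bacteria in boosted medium, fell by 0.61 with malic acid. Both comparisons use the same 3 non-inoculated boosted libraries, on opposite sides, so opposite signs in them are not independent. The same holds for the lists of ribosomal proteins, expansins and glutathione transferases, higher with malic acid and lower with bacteria in boosted medium. The difference between media uses these libraries too. The calls of HB2, a non-symbiotic haemoglobin, and RIXI, a xylanase inhibitor, rest on non-inoculated boosted replicate 2, at 48.6 and 11.4 CPM against 0.0564 and 0.815 CPM (HB2) and 0.789 and 0.560 CPM (RIXI) in replicates 1 and 3. As the label of non-inoculated boosted replicate 2 is in doubt, 1 of the 3 boosted controls may have had bacteria, which bears on the other genes too. Without that library 5141 features passed, 2444 higher and 2697 lower. Without non-inoculated boosted replicate 1 the count of calls was 3699, and without non-inoculated day 3 replicate 1, 2 or 3 the higher features numbered 1912, 1791 and 1832. The boosted roots differ from the standard ones in medium alone per the labels, and whether both sets were handled together is not stated. Their libraries differed in make-up too. Ribosomal RNA took 0.166%, 0.420% and 0.177% of the non-inoculated boosted libraries and 0.309%, 0.333% and 0.412% of the non-inoculated standard day 3 libraries. Whether this bears on the malic acid calls was not tested.

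**Figure D4:**
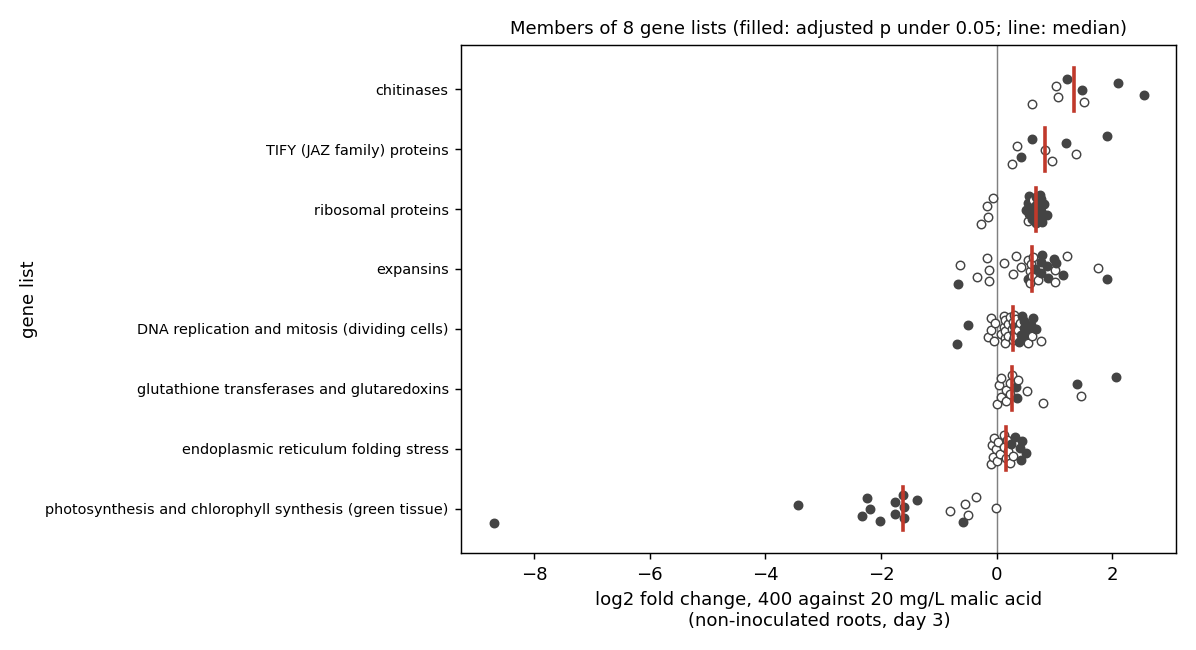
Log2 change of each member (points) of the 8 gene lists that passed the list test between 400 and 20 mg of malic acid per litre in non-inoculated roots at day 3, filled where past the adjusted p threshold, with each list's median as a line. Medians run from 1.34 for chitinases to -1.61 for photosynthesis genes; the lowest point is RBCS, whose fitted change is no bound, since it had almost no reads in 400 mg per litre.

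The last comparison set day 7 against day 1 without bacteria, in seedlings 12 and 6 days old. As reads may have been counted differently at day 1, this comparison cannot separate age from counting. Cellulose synthases of the primary wall fell: CESA6 from 867 ± 57.6 to 244 ± 12.7 CPM (log2 -1.83, edgeR adjusted p = 6.44e-10), with 605 CPM at day 3, CESA5 from 432 ± 20.8 to 160 ± 7.87 CPM (339 at day 3) and CESA1 from 1441 to 495 CPM (1004 at day 3). The haemoglobin HB1 fell from 24.8 ± 12.0 to 0.225 CPM (1.55 at day 3) and the alcohol dehydrogenase ADH1 from 110 to 24.4 CPM (45.2 at day 3). LIR1, a light-regulated gene, rose from 5.57 ± 3.61 to 90.4 ± 9.53 CPM (17.5 at day 3; log2 4.02), the kinase CIPK10 from 209 to 1328 CPM (272 at day 3) and the phosphate transporter PHT1-1 from 46.7 to 214 CPM (98.9 at day 3). Of 24848 features 14222 passed (edgeR), 7820 higher and 6402 lower, but 822 of the higher ones had no read in the 6 day 1 libraries. Without features that had no read there 13500 passed, 6339 higher and 7161 lower. That omission cannot remove features that may have lost only part of their reads at day 1. Day 7 against day 3 gave 7678, 3598 higher and 4080 lower.

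Of 46 lists 7 passed with age, and none with an estimated correlation. Of 9 cellulose synthases 6 fell and 1 rose (median log2 -1.30, adjusted p = 0.00211, adjusted p = 0.695 with an estimated correlation). Of 12 ascorbate peroxidases, catalases and superoxide dismutases 9 fell (median -0.67, adjusted p = 0.00563, adjusted p = 0.197 with an estimated correlation), among them APX6 from 90.6 to 43.9 CPM and SODA from 180 to 92.1 CPM. Of 40 genes of DNA replication 24 fell and 3 rose (median -0.41, adjusted p = 0.0114). Of 29 ribosomal protein genes 18 fell and 1 rose (19 and 1 adjusted over the list alone; median -0.52, adjusted p = 0.0114). Of 21 genes of endoplasmic reticulum folding 14 fell and 2 rose (median -0.30, adjusted p = 0.0294). With an estimated correlation these 3 lists had adjusted p = 0.695, adjusted p = 0.772 and adjusted p = 0.695. Of 18 photosynthesis genes 15 rose and 1 fell (median 2.54, adjusted p = 0.0206, adjusted p = 0.695 with an estimated correlation); the day 1 control that held 31.1 CPM of RBCS is among the libraries compared. Of 11 common symbiosis and strigolactone genes 5 rose and 2 fell (median 0.88, adjusted p = 0.0294, adjusted p = 0.197 with an estimated correlation). D14L_1, of the last list, lay at 2.78 CPM at day 1, 139 at day 3 and 135 at day 7, but D14L_2, the symbol paired with it, had no read at day 1, so a difference in how reads were counted is not excluded for this step. Against day 3 the lists of cellulose synthases (median -1.04, adjusted p = 1.18e-08), DNA replication (-0.15, adjusted p = 0.0258) and photosynthesis (0.83, adjusted p = 0.0258) passed in the same direction, but not with an estimated correlation (adjusted p = 0.555, adjusted p = 0.661 and adjusted p = 0.661). Those of symbiosis genes, ribosomal proteins, folding and peroxide removal had adjusted p = 0.859, 0.382, 0.930 and 0.0653.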

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

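The tests of the boosted replicate 2 libraries and the splits of the 6 compared libraries were chosen after the result was seen, as was the blocked fit of day 1 whose splits are given; the splits of the 24-library fit were planned.

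The inoculation effect differed between boosted and standard medium for 6 gene lists, by a test of the difference itself with a preset correlation, but for 0 with an estimated correlation or by fry. With no filter, without non-inoculated day 3 replicate 2 and without non-inoculated boosted replicate 1 it was 1 list each. With the stricter filter it was 3 lists, and without both boosted replicate 2 libraries 11. The median difference on the log2 scale was -0.69 for diterpenoid phytoalexin synthesis, -0.72 for chitinases, -0.23 for expansins, 0.20 for HAK and HKT potassium transporters, -0.20 for glutathione transferases and glutaredoxins and -0.31 for ribosomal proteins. No single feature passed in edgeR (0 of 24848; 1467 at an unadjusted p under 0.05, 2 by DESeq2, 1 by limma-voom with quality weights).

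The boosted replicate 2 libraries lay across their groups. Of 77 genes that had at least 0.9 of the pairs of 1 inoculated and 1 non-inoculated library of the standard medium in order, 6 were ordered by the boosted labels and 40 with replicates 1 and 3 labelled inoculated and replicate 2 labelled non-inoculated on the inoculated side, where chance gives 3.85 for each of 20 orders. The total reads of these 2 sets of 3 libraries overlap (a gap of -1.72 megareads), which argues against library size. Both replicate 2 libraries held more ribosomal RNA (0.297% and 0.420%) than the other boosted libraries (0.133% to 0.177%). They also held more non-coding reads (0.998% and 1.39% against 0.433% to 0.570%). In the standard day 3 libraries ribosomal RNA took 0.287% to 0.412% and non-coding features 0.964% to 1.41%. By these measures the replicate 2 libraries lay nearer to the standard libraries than the other boosted ones did. Whether this make-up bears on the order was not tested. An exchange of the labels of both replicate 2 libraries may account for the order, as may a state of the roots that varied between cultures, for which the test was not decisive: at 1 of 3 days another order also held more genes than the labelled one (53 against 50 of 428 at day 1, 21 against 45 of 173 at day 3, 55 against 77 of 350 at day 7). HB2, ZIP1 and ADH2, chosen after their values were seen, show it: the libraries labelled inoculated held 53.4, 0.148 and 72.7 CPM of HB2 and those labelled non-inoculated 0.0564, 48.6 and 0.815, for ZIP1 39.98, 3.84 and 52.2 against 6.59, 38.9 and 6.47, and for ADH2 1276, 697 and 2039 against 583, 2033 and 613.

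Other splits of the same libraries were counted for each comparison. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In the 24-library fit the real split gave 5 calls at day 1 (1 split as large, highest other 2), 0 at day 3 (10 splits, highest other 0), 0 at day 7 (10 splits, highest other 1), 62 in boosted medium (3 splits, highest other 739), 5892 for malic acid (1 split, highest other 0) and 14222 for age (1 split, highest other 0). The split with 739 calls in boosted medium set inoculated replicates 1 and 3 with non-inoculated replicate 2, the order described above, and another with 517 set inoculated replicates 1 and 2 with non-inoculated replicate 3; both point to a structure of the samples. In the fits of the compared 6 libraries the real split gave 0 calls at day 1 (10 splits, highest other 0), 156 at day 3 (1 split, highest other 0), 0 at day 7 (10 splits, highest other 0) and 0 in boosted medium (10 splits, highest other 264, by the same split as the 739). The blocked fit of day 1 gave 670 calls and the other exchanges within pairs at most 0, over 4 ways, also too few. For the difference between media 40 of 40 splits gave as many as the real 0 (highest other 188), and between days 40 of 40 (real 0, highest other 2). Where the real count is 0 every split gives as many, so those counts say nothing about chance. The 188 calls point to a structure of the samples too.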

How the results depend on the processing

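The alternatives limma-voom, the nested block, the block with the compared groups alone, the 18 libraries, the omitted pairs of libraries, the settings for age and every list test except the replicate block, the estimated correlation and fry, and the overlaps except those at stricter thresholds, were chosen after the result was seen; the cause was not tested unless stated. Under DESeq2 size factors, no filter, the stricter filter and no robust spread each count of called features stayed within 1.5 times its value, but in boosted medium the directions moved more: 72 higher and 20 lower with DESeq2 size factors, 31 and 11 with no filter and 70 and 21 with the stricter filter. The DESeq2 test gave 71 calls at day 1 (18 higher, 53 lower), 8 at day 3, 101 at day 7 (86 and 15), 751 in boosted medium (571 and 180), 2 for the difference between media and 2 between days. The replicate block gave 8, 1 and 30 at day 1, day 3 and boosted. Limma-voom with quality weights gave 27, 100, 7 and 31 for the 4 inoculation effects, 10438 for malic acid and 1 for the difference between media. The nested block gave 6 at day 1, 1 at day 3, 6 for boosted and 1 for the difference between media. Without both boosted replicate 2 libraries there were 56 calls at day 1, 550 for boosted (219 and 331), 49 for the difference between media and 1 between days. Without both day 1 replicate 1 libraries there were 2 at day 1, 1 at day 3 and 164 for boosted. The 18 libraries of the standard medium gave 51 at day 1. The compared groups alone gave 0, 156 and 0 at day 1, day 3 and boosted, and with a block 670, 276 and 0. The fall at day 3 from 156 to 0 calls was tested by adding 1 other group at a time to the 6 libraries. The inoculated day 7 group, with the largest spread, left 0 calls and the inoculated boosted group 0. The inoculated day 1 group left 24, the non-inoculated day 1 group 8 and the non-inoculated boosted group 21. The non-inoculated day 7 group, with the smallest spread of those added, gave 200. A shared error raised by groups with a larger spread may thus account for the fall, although the groups in between did not follow the order of their spread. Day 3 in place of day 1 gave 7678 for age.

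Lists called with an estimated correlation were 1 at day 1 and 0 in each of the other 6 comparisons. Fry called 1 at day 1, 0 at days 3 and 7, 1 for boosted, 13 for malic acid, 0 for the difference between media and 31 for age. At day 3 no filter gave 2 lists, the compared groups 9, and 10 with a block. Without both boosted replicate 2 libraries 11 lists passed for boosted and 11 for the difference between media, where no filter gave 1 and the stricter filter 3. Overlapping calls, 0 at first, were 11 by DESeq2, 1 with the block, 4 by limma-voom, 1 with the nested block, 22 without both boosted replicate 2 libraries, 1 without both day 1 replicate 1 libraries and 33 with the compared groups and the block at day 1, over all features each fit tested. Stricter thresholds can take nothing from 0, so they were no test of it.

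Leaving out 1 library gave 0 to 5 calls at day 1, 0 to 2 at day 3, 0 to 236 at day 7, 0 to 1281 for boosted, 3699 to 5141 for malic acid, 0 to 80 for the difference between media, 12926 to 13462 for age and 0 to 0 between days, and 2 to 8, 3 to 6, 9 to 15, 2 to 11, 6 to 8, 1 to 8 and 7 to 10 lists for days 1, 3 and 7, boosted, malic acid, the difference between media and age. Day 1 had 2 higher and 2 lower without inoculated replicate 1, 0 and 5 without non-inoculated replicate 1, 0 calls without inoculated or non-inoculated replicate 2, 1 without inoculated replicate 3 and 3 without non-inoculated replicate 3. Day 3 had 2 without inoculated replicate 1, and day 7 had 236 without inoculated replicate 1. Boosted had 27, 111 and 1281 without inoculated replicates 1, 2 and 3, and 41 and 0 without non-inoculated replicates 1 and 3. Malic acid had 3699 without non-inoculated boosted replicate 1, and 1912, 1791 and 1832 higher without non-inoculated day 3 replicates 1, 2 and 3. The difference between media had 1, 80 and 1 without inoculated boosted replicates 2 and 3 and non-inoculated boosted replicate 1. Lists at day 1 fell to 2 without inoculated replicate 1 or non-inoculated replicate 3, at day 3 to 3 without inoculated replicate 1, at day 7 to 9 without inoculated replicate 3. For boosted they were 11, 2, 3 and 9 without inoculated replicates 2 and 3 and non-inoculated replicates 1 and 2. For the difference between media they were 2 and 1 without inoculated and non-inoculated day 3 replicate 2, and 3 and 1 without inoculated boosted replicate 3 and non-inoculated boosted replicate 1.

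The log2 changes of named genes under the alternatives were set against the 24-library fit, and 0 reversed where either fit called the gene. Of genes with a symbol that fit called 1 at day 1 and 0 at day 3. An uncalled gene counted as the same if it stayed uncalled within 1 SE. At day 1, 767 of 836 values were the same, 3 were weaker, 52 became calls and 14 moved by more. At day 3, 322 of 361 were the same, all without a call, and 39 became calls. In boosted medium 50 of 72 kept their call and direction, with 22 weaker. For malic acid 1468 of 1672 did so, with 204 weaker, and for age 2543 of 2596, with 53 weaker. A feature at 1 CPM has 12.9 reads in the smallest library, which limits what can be seen below that level.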

Other observations

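The tests of the features without a read at day 1 and of those absent at day 3 were all chosen after the result was seen.

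AMY1.1, an alpha-amylase gene of the germinating seed, was chosen after its values were seen: it had 26.8 CPM in non-inoculated day 1 replicate 1, 0.207 and 0 in the other two, 41.3 in inoculated day 7 replicate 3 and 4.86 in non-inoculated day 7 replicate 1. The same non-inoculated day 1 replicate 1 held 31.1 CPM of RBCS against 0 and 0.0745, and 21.8 CPM of RBCS-A against 0.622 and 1.79. Small heat shock proteins and HSP100 had a median log2 change of -0.21 with bacteria at day 3 in the 6-library fit (13 genes, adjusted p = 0.0124, adjusted p = 0.475 with an estimated correlation). At day 7 against day 3 without bacteria, SWEET sugar transporters were lower with a preset correlation (10 genes, median log2 -1.11, adjusted p = 0.0258), as were expansins (32 genes, -0.62, adjusted p = 0.013), beta-glucosidases (16 genes, -0.50, adjusted p = 0.0258) and PIN auxin transporters (7 genes, -0.78, adjusted p = 0.0258). Immune receptors, kinases and regulators were higher (23 genes, median 0.27, adjusted p = 0.0258). None passed with an estimated correlation (adjusted p = 0.330 for SWEET genes and adjusted p = 0.585 for the others).

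In the 6 day 1 libraries 316 features had no read although they held at least 1 CPM in all 18 later libraries. Library depth is argued against as the cause, since a feature at 1 CPM has 83.9 reads over the 6 libraries. Reads shared between near-identical features may not have been counted at day 1: of the 20 features whose counts matched another feature within 5% in each of the 18 later libraries, 100% had no read at day 1, against 275 of 18612 other features (1.48%; Fisher's exact test, p = 5.12e-37). A feature set without non-coding genes may have been used for these libraries, since 0 of 2957 non-coding features had a read there. The 20 matched features were not limited to coding ones, and such a set by itself would leave any non-coding ones without a read. Matched features also are not independent of each other. The exact test therefore cannot tell these explanations apart. Age, which the design confounds with the day 1 libraries, stays open for single genes and was not tested.

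Over the 12 day 3 libraries 9 features stayed under 1 CPM although they held at least 2 CPM in all 12 others: OPR4 (0.138 to 0.781 against 17.005 to 63.5 CPM) and 8 loci, all 8 on chromosome 11 by their identifiers, with 81 tested loci between the first and the last. In 10000 draws of 8 tested loci at most 6 shared a chromosome (permutation p = 1e-04, the smallest these draws can give). That 5 of the 9 had a read at day 3 argues against a feature set that left them out, for these 5; the other 4 had no read. A sequence difference in the plants of the day 3 harvest, such as another seed lot, may account for the 8 loci, and joint regulation of neighbouring genes and the age of the seedlings stay open as untested. The same rule gave 355 features absent at day 1 and 0 at day 7, and 1 feature present at day 3 alone (OS06G0215950, 9.08 to 22.8 CPM against at most 0.288), 6 at day 7 alone and 0 at day 1 alone.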
